A study of Homo sapiens with 44 samples.

How the data were processed

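The samples were HepG2 cells, an established human hepatoma line, that carried Cas9 and 1 single guide RNA (sgRNA) per line. Of the 24 lines, 1 carried a control sgRNA (sgCTRL) and the other 23 carried an sgRNA named after its target. Each line was kept in serum (DMEM with 10% fetal bovine serum) or was starved overnight in optiMEM with no serum, and RNA was taken on day 2, per the labels. There were 44 samples, 23 in serum and 21 serum-starved, and 20 lines (sgCTRL included) had both conditions. The lines sgCSK, sgDR1 and sgINTS1 were measured in serum only, and sgYTHDC1 in the starved condition only. The labels' protocols state that the replicates are biological, 2 per line and condition. The series table holds 86 replicate columns, since sgDDX28 has 1 in each condition.

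Libraries were made from polyA RNA with Lexogen QuantSeq-Pool, which tags transcripts near their 3′ end, and were sequenced on an Illumina NextSeq, per the labels' protocols. RNA was taken with either of a pair of kits, and which kit served which sample is not given in the sources used here. The submitters' processing notes name STAR 2.5.2b, HTSeq 0.9.1, DESeq2 1.26.0 and the genome build GRCh38.p12, without saying what each was used for. The authors deposited a table of RPM (reads scaled to a common total per library) for 8971 genes and 85 STAR junction files with counts of uniquely mapped reads across splice junctions. The serum sgACAD11 replicate 1 library has no junction file here. Per the file headers, the 86 columns used share a single batch heading. Another 54 columns of per-sample values belong to no sample of this series and were not used. Of the 8971 genes, 579 had no value for these samples and 8392 remained. Several genes of interest are not among them: ACAD11, ATP6V1G2, DEF6, GBA, INTS1, INSIG1, MYLIP, TEN1 and the micro-RNA gene MIR5089.

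The deposited RPM of a library were whole multiples of a fixed step, the RPM of 1 read, within a tolerance of 0.05 reads. The step was sought over values up to 200 RPM, and 99.99% of all values above 0 came out whole. It gave 344431 to 3181318 reads behind the RPM per library (median 1160654), so that 1 read was worth 0.314 to 2.903 RPM (median 0.862). Of the 86 libraries, 34 lay below the reads per sample that the labels state. The RPM summed to between 945548 and 982120 per library. Annotated junction reads numbered 38418 to 358758 per library (median 131990), and 99.86% to 99.94% of them lay at introns of GENCODE release 29, whose gene names and GRCh38 coordinates were used. Junction reads were summed per gene. At most 5.2% of them in any library were shared by overlapping genes and were left out.

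The serum comparison used limma 3.58.1 in R 4.3.3 on log2(RPM + 1). Replicate columns were averaged to 1 value per sample, genes needed a mean of 5 RPM, and the 20 lines with both conditions were paired. Every fold is therefore on the log2(RPM + 1) scale, which understates the change of low genes. For the sgRNA comparisons, limma was fitted over all 86 libraries with 1 group per line and condition (42 residual degrees of freedom), and each line was set against sgCTRL as the average over the conditions they share. An SD given over 4 libraries of a line pools its serum and starved libraries, so it includes the difference between the conditions. A second limma contrast tested whether a line's difference from sgCTRL differed between the conditions. All limma fits used a trend of the spread with the mean. Junction reads were tested with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr and TMM. P-values are adjusted by Benjamini and Hochberg, within each line for genes, and a gene is called where the adjusted p is under 0.05.

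Gene lists were written from textbook knowledge, and 33 with 3 or more measured members were tested with camera at a preset correlation of 0.01 and again with the correlation estimated. The p-values were adjusted over the 33 lists in the serum comparison, and over all 759 pairs of list and line in the sgRNA comparisons. Targeted genes were ranked among all lines of a condition and tested with a one-sided permutation test of 100000 resamples. The design, the lists, the alternatives other than those named as added, and the rule for the genes named were chosen before the data were examined. For the serum comparison the rule takes the 8 largest rises and the 8 largest falls among called genes with a mean of 20 RPM and the same sign in 17 of the 20 lines, and up to 4 called members per list. For sgRNA lines it takes the target, LDLR, PCSK9, HMGCR, HMGCS1, APOB and SREBF2. For the 6 lines with the most called genes and for sgLDLR and sgMYLIP it adds the 5 largest rises and falls with a mean of 20 RPM, and for each list called up to 4 called members.

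Alternatives were pseudocounts of 0.25 and 5 RPM, no filter or a mean of 20 RPM, median-of-ratios and quantile scaling, an unpaired serum fit, the mean of all other lines in place of sgCTRL for genes, edgeR on the whole reads recovered from the RPM for the serum comparison, the replicate number as a block, DESeq2 1.42.0 on junction reads, and leaving out each line, condition or replicate. Added after seeing the data were the recovered reads for the sgRNA lines, the mean of all other lines as the reference for the lists, fits without the 5 libraries under 500000 reads, pseudocounts for the test of the difference between conditions, a correction for transcript length, and the lists under the left-out replicates. A replicate left out of a line removes its serum and its starved library together.

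Each step was tested on simulated data with 200 changed genes. For a line against control with 4 libraries each (8377 genes), limma recovered 52% to 56% of the 2-fold changes and 92% to 100% of the 4-fold changes. For the paired serum comparison it recovered 100% of both. For the difference between conditions it recovered 8% to 10% of the 2-fold and 50% to 60% of the 4-fold changes. For a line against control on junction reads (1414 genes), edgeR recovered 48% to 58% and 90% to 100%. In these sets limma also called 22 unchanged genes for a line against control and 7 for the difference between conditions, each more than 5% of its calls. It called 5 for serum, and edgeR on junction reads called 8 for a line. An unchanged line gave 0 genes (8377 tested) and 0 lists (33 tested). Genes were simulated as independent, with no structure shared between libraries, so these counts do not bound false calls in the real libraries. Drawing and tables used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.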

Results

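The study asked which genes govern cholesterol uptake, and its lines carry sgRNAs against genes of that question in HepG2, a hepatoma line that keeps many hepatocyte functions. 3′ mRNA profiles were collected from 24 lines, in serum (23 lines) and after overnight serum starvation (21 lines). The 86 libraries rested on 344431 to 3181318 reads each (median 1160654). The main axis of variation was the culture condition: the first principal component held 15.4% of the variance, and serum accounted for 0.94 of it (R²). The second held 9.5%, and serum accounted for none of it. It correlated with the log of depth (Pearson r = 0.46), and replicate number accounted for 0.17 of it (R²). Replicate number accounted for 0.2 of the third, which held 5%. Replicate libraries of 42 samples differed by more than counting noise, with a chi-square per degree of freedom of 2.22 to 15.92 (median 5.11), so none was a copy of another. P-values rest on this spread between replicates, or on that between lines.

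Targeted mRNAs were lower in their own line more often than chance gives. DDX28, a mitochondrial RNA helicase (chromosome 16, 68021274 to 68023442), stood at 4.01 RPM in serum and was listed at 0 after starvation in its own line, against 12.42 and 10.99 RPM in sgCTRL (log2 -2.47). That line has 1 library per condition, where 1 read is worth 1.0027 and 1.5653 RPM, so the fold depends on the pseudocount. CSK, a kinase that restrains SRC (chromosome 15, 74782057 to 74803198), stood at 21.5 RPM against 36.4. SOD1, the cytosolic superoxide dismutase (chromosome 21, 31659622 to 31668931), stood at 615 and 718 RPM against 721 and 1007. OST4, a small subunit of the oligosaccharyltransferase (chromosome 2, 27070472 to 27071773), stood at 1146 and 1252 RPM against 1318 and 1560. LDLR, the receptor that takes up LDL (chromosome 19, 11089362 to 11133816), stood at 49 RPM in serum against 56.1, and at 59.1 after starvation against 133, where the median over lines was 92.83. DR1, a repressor of transcription (chromosome 1, 93345888 to 93369498), stood at 31.5 RPM against 45.1.

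Some targets were near or above the level of sgCTRL. HYOU1, an ER chaperone (chromosome 11, 119044189 to 119057202), was higher in its own line, with 200 and 206 RPM against 130 and 179. HNF1A, a liver transcription factor (chromosome 12, 120978543 to 121002512), stood at 9.26 RPM against 21 in serum and at 12.3 against 12 after starvation. PREB, which loads the COPII coat (chromosome 2, 27130756 to 27134675), stood at 160 and 106 RPM against 156 and 125. RBM14 stood at 21 and 17.6 RPM against 18 and 19.7, and YTHDC1 at 19.2 against 18.9. The targets SLC39A3 (29.7 and 21.2 against 41.5 and 36.6), TMED2 (198 and 194 against 236 and 225), KLHDC3 (97.8 and 102 against 133 and 153) and ATP13A1 (12.2 and 13.1 against 16.1 and 23.7 RPM) lay below sgCTRL. Over 27 pairs of line and condition from 15 lines, ranks among all lines summed to 165 where chance gives 311 (one-sided permutation p = 1e-05, the smallest these resamples can give). Lines were permuted separately in each condition, so a line with both conditions counted as independent pairs and the p is likely too small. The target was the lowest of all lines in 9 pairs. Junction reads were too few to rank most targets, with 226 reads for OST4, 128 for SOD1, 8 for HYOU1 and 0 to 3 for each other target in its own line. Where in each gene the guide lies is not given in the sources used here. The tags lie near 3′ ends and can fall outside an edit, and an edit need not lower the mRNA, so a level near that of sgCTRL does not test whether a gene was disrupted. The targets of sgACAD11, sgATP6V1G2, sgDEF6, sgGBA, sgINTS1, sgMIR5089, sgMYLIP and sgTEN1 have no value here.

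**Figure D1:**
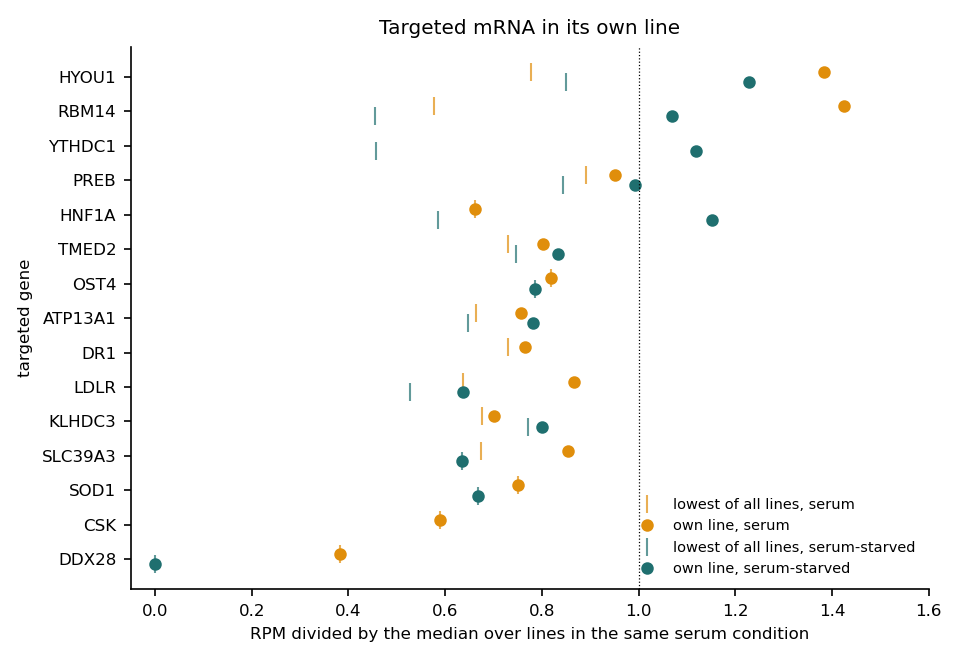
RPM of each targeted mRNA in its own line, divided by the median over all lines of the same condition (points; orange serum, teal serum-starved), with the lowest of all lines as ticks and the median of all lines as the dotted line at 1. DDX28, CSK and SOD1 points lie on the tick of the lowest line, and both HYOU1 points lie above 1.

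Serum starvation changed the mRNA of sterol and fat synthesis, of hepatocyte secretion, and of metal and oxidative stress defence across the lines, as lists at the preset correlation. Starved cells were kept in optiMEM and the others in DMEM, so removal of serum and change of medium cannot be told apart. Serum starvation stands for both throughout. With an estimated correlation the NRF2 list of oxidative stress was called (camera adjusted p = 0.0165), and those of cholesterol synthesis (0.2), fatty acid synthesis (0.2), secreted proteins (0.0705) and metallothioneins (0.0867) were not. HMGCS1, which makes HMG-CoA for the mevalonate path, rose from 200 ± 42.2 RPM to 367 ± 49.3 (SD, n = 20 lines), and LDLR rose from 56.9 ± 9.26 to 95.8 ± 23 RPM. NQO1, an NRF2-driven quinone reductase, rose from 344 ± 47.7 to 1025 ± 98.8 RPM. The metallothionein MT1G, which binds zinc and copper, rose from 129 ± 242 to 1370 ± 442 RPM, where the serum mean includes 975.4 and 1319 RPM in the libraries of sgLDLR. TTR, the secreted carrier transthyretin, fell from 1168 ± 186 to 489 ± 78 RPM. In limma, 4224 of 8388 genes were called, 1957 higher and 2267 lower in starved cells, of which 68 and 122 changed at least 2-fold. With median-of-ratios scaling the split was 2162 and 2142, with quantile scaling 2169 and 2069, and the median gene moved by -0.02 on the log2 scale.

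The largest rises were in MT1B (0.307 ± 0.505 to 59.7 ± 28.8 RPM, SD, n = 20 lines, log2 5.42, limma adjusted p = 4.73e-28), MT1G (log2 4.06, limma adjusted p = 4.96e-28), LAIR2 (log2 2.42) and MT1F (log2 2.33, higher in 19 of 20 lines). SPP1, which encodes the secreted osteopontin, rose from 58.8 ± 21.1 to 250 ± 77.5 RPM (SD, n = 20 lines, log2 2.09, limma adjusted p = 4.98e-31). CPLX2 rose by 2.06, the kinase anchor AKAP12 by 1.85 and the tight junction gene CLDN4 by 1.71 on the log2 scale. The deepest fall was that of HAMP, which encodes the iron hormone hepcidin, from 75.3 ± 88 to 1.51 ± 1.12 RPM (SD, n = 20 lines, log2 -4.62, limma adjusted p = 5.65e-30). G6PC1, the last enzyme of glucose release, fell from 52.3 ± 16.4 to 3.74 ± 1.71 RPM (log2 -3.53), and FST, the secreted activin antagonist follistatin, from 272 ± 30.8 to 39.1 ± 6.86 RPM (log2 -2.78, limma adjusted p = 2.06e-38). DEPP1, a FOXO target, fell from 319 to 45.5 RPM (log2 -2.82). PAQR8 (log2 -2.39), the protease FURIN (-1.90), RAB17 (-1.89) and ELP1 (-1.64) followed. All of these except MT1F had the same sign in 20 of 20 lines. Metallothionein genes are near-identical copies, and which copy a 3′ tag came from is uncertain.

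Of 20 cholesterol synthesis genes, 13 rose and 2 fell, the same numbers as adjusted over the list alone. The median was 0.32 on the log2 scale (camera adjusted p = 2.39e-06, adjusted p = 0.2 with an estimated correlation). HMGCS1 rose by 0.89, ACAT2 and FDFT1 by 0.71 each, and HMGCR, the rate-limiting enzyme, from 119 ± 20.7 to 190 ± 25.6 RPM (SD, n = 20 lines, log2 0.68). Of 14 genes of LDL uptake and sterol sensing, 5 rose and 2 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.402). LDLR rose by 0.72 (limma adjusted p = 3.32e-15) and PCSK9, which sends LDLR to lysosomes, by 0.48 in 19 of 20 lines, while the receptor LRP1 fell by 0.92. Among 13 fatty acid synthesis genes, 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000382, adjusted p = 0.2 with an estimated correlation). FADS2 rose by 0.89, ACLY by 0.75 and SCD by 0.68, and GPAM, which starts triglyceride assembly, fell by 0.96. Among 8 LXR targets, 2 rose and 3 fell (3 and 3 adjusted over the list alone), with no call for the list (camera adjusted p = 0.663). PLTP rose by 0.43 and SMPDL3A fell by 0.88.

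Genes of the differentiated hepatocyte mostly fell. Of 19 secreted proteins, 13 fell and none rose, also adjusted over the list alone (camera adjusted p = 1.7e-07, adjusted p = 0.0705 with an estimated correlation). Albumin mRNA (ALB) fell from 20980 to 12520 RPM (log2 -0.75), TTR by 1.25, KNG1 by 1.27 and ITIH3 by 1.36. Of 14 HNF1A-dependent genes, 12 fell and none rose, also adjusted over the list alone (camera adjusted p = 2.67e-06, and adjusted p = 0.037 with an estimated correlation), among them DPP4 (-1.01), AGXT (-0.80) and the glucose transporter SLC2A2 (-0.71). Of 8 acute phase genes, 5 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.25 with an estimated correlation). HAMP, FGL1 (-0.70) and CFB (-0.49) fell and ORM1 rose by 0.56. Of 24 genes of ER to Golgi transport, 14 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.216 with an estimated correlation), led by PREB (-0.60) and SEC24D (-0.56). APOB, the scaffold of VLDL, fell from 1206 to 875 RPM (log2 -0.46), APOM by 0.53 and APOA5 by 0.48, and APOA4 rose by 0.98. The 11 apolipoprotein genes (6 fell, 3 rose) were not called as a list (camera adjusted p = 0.111, but 0.0173 with quantile scaling).

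Several lists of stress and growth genes were higher at the preset correlation, while the unfolded protein response was not called (9 of 19 rose and 2 fell, also adjusted over the list alone, camera adjusted p = 0.101). Of 13 NRF2 targets, 11 rose and 2 fell, also adjusted over the list alone, with a median of 0.74 (camera adjusted p = 2.01e-07, and adjusted p = 0.0165 with an estimated correlation). NQO1 rose by 1.58 (limma adjusted p = 1.53e-34), AKR1B10 by 1.49 and G6PD by 0.84, and AKR1C1, whose tags can be shared with AKR1C2, fell by 1.17. Of 11 metallothionein and zinc genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.000401, adjusted p = 0.0867 with an estimated correlation). Of 16 ATF4 response genes, 13 rose and none fell, also adjusted over the list alone (camera adjusted p = 5.15e-07, adjusted p = 0.0705 with an estimated correlation), with DDIT4, an inhibitor of mTORC1, rising from 38.3 to 114 RPM (log2 1.54), TRIB3 by 0.74 and SLC3A2 by 0.71. Of 18 genes of glycolysis and hypoxia, 12 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 2.47e-06, adjusted p = 0.0999 with an estimated correlation), with ADM at 1.38, CA9 at 0.81 and GAPDH at 0.52. Of 16 mitosis genes, 14 rose, also adjusted over the list alone (camera adjusted p = 4.83e-06, adjusted p = 0.145 with an estimated correlation), with CDC20 at 0.86 and CCNB1 at 0.80. Of 15 DNA replication genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.351 with an estimated correlation), with RRM2 at 0.83.

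Of 12 immediate early genes, 7 rose, also adjusted over the list alone, with EGR1 from 5.61 to 16.9 RPM (log2 1.56) and JUN at 0.85 (camera adjusted p = 0.00172, adjusted p = 0.0999 with an estimated correlation). Of 8 FOXO and insulin-repressed genes, 6 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00321, adjusted p = 0.0743 with an estimated correlation). G6PC1, PCK1 (-1.14), BCL6 (-0.93) and PPARGC1A (-0.75) fell, of which G6PC1 and PCK1 serve gluconeogenesis. Of 11 progenitor and biliary markers, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 8.84e-05, and adjusted p = 0.0261 with an estimated correlation), with LGALS1 at 1.03 and KRT19 at 0.96. Of 11 heat shock genes, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000294, adjusted p = 0.0705 with an estimated correlation), with HSPE1 from 1260 to 2009 RPM (log2 0.67). Of 20 ribosomal protein genes, 7 rose and 1 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.25 with an estimated correlation), a small shift that quantile scaling turned to 5 rising and 7 falling (camera adjusted p = 0.646). Camera called 17 of the 33 lists, 12 higher and 5 lower, and 3 of the 17 (NRF2, HNF1A-dependent and progenitor lists) with an estimated correlation. With a mean of at least 20 RPM, the calls of acute phase, FOXO, immediate early, DNA replication and ribosomal protein genes were lost.

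**Figure D2:**
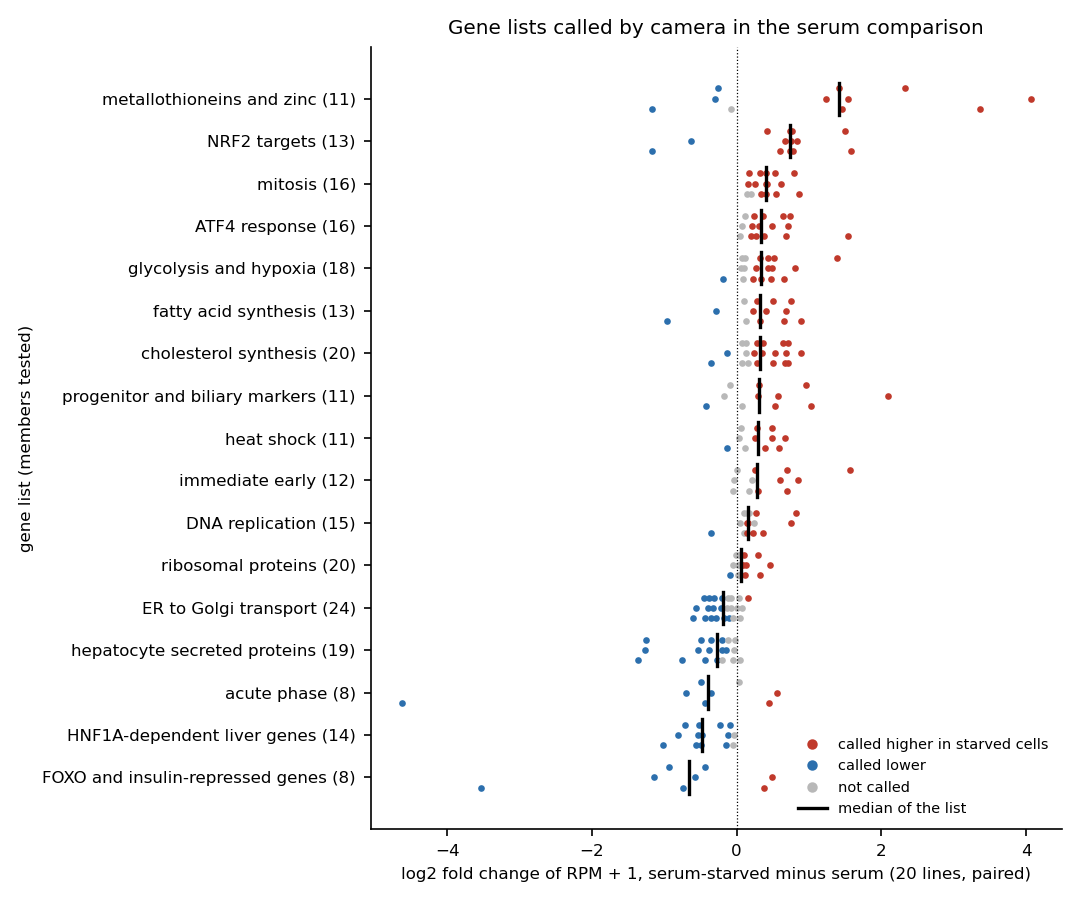
Log2 change of RPM + 1 from serum to serum-starved cells (x axis) for each tested member (points) of the 17 called gene lists (y axis, members tested in parentheses), as a paired mean over 20 lines. Black bars mark list medians, which range from 1.413 for metallothioneins to -0.657 for FOXO and insulin-repressed genes, red and blue points are genes called higher and lower, and quantile scaling turns the small ribosomal protein median from 0.06 to -0.043.

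Junction reads are spliced reads of the same libraries. With edgeR, 519 of 1339 genes were called (257 higher and 262 lower in starved cells). Of these, 376 were also called from RPM in the same direction and 28 in the opposite one. Of the 884 genes called from RPM that junction reads could test, 729 had the same sign. Leaving out any 1 line, 4090 to 4275 genes were called.

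The lines differed widely from sgCTRL in how many genes moved. Summed over the 23 lines, limma called 1193 differences (727 higher and 466 lower). The most were in sgOST4 (316 higher, 164 lower) and sgHYOU1 (116 and 85), whose targets act in the ER, followed by sgCSK (66 and 53), sgDR1 (46 and 16), sgSOD1 (27 and 35), sgHNF1A (40 and 19), sgLDLR (37 and 17), sgPREB (19 and 27), sgINTS1 (35 and 1) and sgRBM14 (19 and 17). The lines sgDDX28 (0 and 11), sgMYLIP (0 and 10), sgSLC39A3 (4 and 1), sgACAD11 (0 and 4), sgDEF6 (1 and 3), sgYTHDC1 (0 and 2), sgGBA (0 and 1) and sgTMED2 (1 and 0) had few. In 5 lines limma called 0 genes, with 564 (sgATP13A1), 638 (sgATP6V1G2), 750 (sgKLHDC3), 561 (sgMIR5089) and 503 (sgTEN1) of 8388 at an unadjusted p under 0.05, and edgeR on recovered reads called 0, 0, 0, 1 and 0. Junction reads called 19 differences in all.

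The split between higher and lower calls moved with the scaling. With median-of-ratios scaling it was 153 and 250 in sgOST4, 84 and 128 in sgHYOU1, 24 and 38 in sgLDLR, 52 and 31 in sgSOD1, and 620 and 619 in all. With quantile scaling it was 180 and 236, 96 and 127, 25 and 41, 37 and 24, and 499 and 545. The sgINTS1 count of 35 and 1 was 0 and 1 with quantile scaling and 3 and 0 with a pseudocount of 5 RPM, edgeR on recovered reads called 0 there, and 2 of its 36 genes were also called against all other lines. The median over all genes was 0.16 in sgOST4, -0.13 in sgDDX28 and -0.12 in sgMYLIP, and median-of-ratios scaling moved it to 0.03, 0.02 and 0.00. Changes in these lines are to be read against those medians. Lines with both conditions were set against the same 4 sgCTRL libraries, sgCSK, sgDR1 and sgINTS1 against the 2 in serum and sgYTHDC1 against the 2 starved ones, and the total of 1193 ranged from 100 to 2315 when a condition or a replicate was left out.

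**Figure D3:**
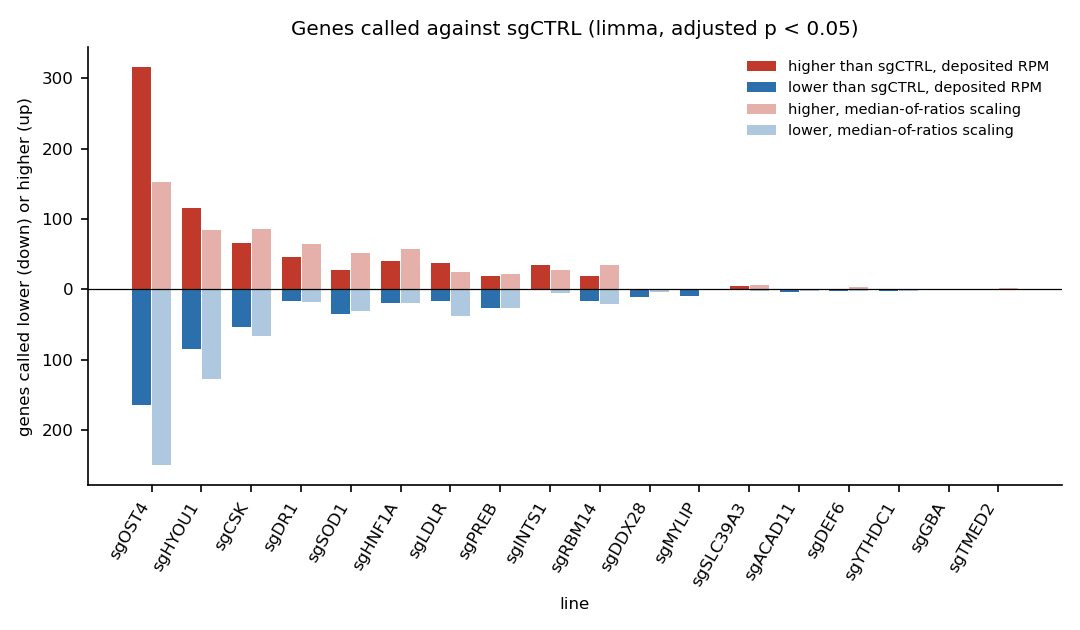
Number of genes called against sgCTRL by limma in each line with at least 1 called gene (x axis), higher upward in red and lower downward in blue, with the deposited RPM (dark bars) and with median-of-ratios scaling (pale bars). In sgOST4 the split of 316 higher and 164 lower turns to 153 and 250 with the rescaled values.

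In sgOST4 the mRNA of hepatocyte secretion, lipoprotein assembly, cholesterol synthesis and hypoxia was lower, and that of biliary markers was higher. KRT19, a keratin of bile duct cells, stood at 585 ± 359 RPM against 125 ± 57.4 in sgCTRL (SD, n = 4 libraries each, log2 2.16, limma adjusted p = 4.57e-09). S100A11 stood at 291 ± 158 RPM against 47.1 ± 17.2 (log2 2.55, limma adjusted p = 1.32e-07). PCSK9 fell to 195 ± 53.2 RPM against 395 ± 56.7 (log2 -1.05, limma adjusted p = 3.01e-06), APOC3, a regulator of triglyceride clearance, to 415 ± 170 against 969 ± 255 (log2 -1.28), and transferrin (TF) to 870 ± 355 against 1793 ± 308 (log2 -1.12). LDLR was close to sgCTRL (log2 -0.03, limma adjusted p = 0.949).

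Of 19 secreted proteins, 12 fell in sgOST4 and none rose (14 and 0 adjusted over the list alone, camera adjusted p = 3.11e-19). Of 11 apolipoprotein genes 5 fell, also adjusted over the list alone (camera adjusted p = 8.82e-10), with APOC3, APOA5 (-1.14) and MTTP (-0.79). Of 20 cholesterol synthesis genes 8 fell (11 adjusted over the list alone, camera adjusted p = 1.17e-13), with SC5D (-0.89), TM7SF2 (-0.80), DHCR7 (-0.71) and HMGCS1 (-0.70). Of 18 genes of glycolysis and hypoxia, 8 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 1.39e-15), with CA9 (9.32 against 38.6 RPM, log2 -1.96), PFKFB4 (-1.67), PDK1 (-1.21) and NDRG1 (-1.19). Of 14 HNF1A-dependent genes 4 fell (7 adjusted over the list alone, camera adjusted p = 1.31e-06), with AGXT at -1.38, and of 8 FOXO and insulin-repressed genes 3 fell (4 adjusted over the list alone, where 1 rose, camera adjusted p = 0.000151), with PCK1 at -1.87 and G6PC1 at -1.53. Of 11 progenitor and biliary markers 7 rose, also adjusted over the list alone, with S100A6 at 1.58 and LGALS1 at 1.04 (camera adjusted p = 1.91e-07). These 7 lists were also called with an estimated correlation (camera adjusted p from 0.0139 to 0.0418).

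Further lists of sgOST4 were called at the preset correlation alone. Of 13 SRF and YAP targets, which include contractile genes, 7 rose (10 adjusted over the list alone, camera adjusted p = 7.55e-06, adjusted p = 0.113 with an estimated correlation), with TAGLN at 64.9 ± 30 RPM against 14.6 ± 10.3 (SD, n = 4 libraries each, log2 2.63), ANKRD1 (log2 2.08) and CCN1 (log2 1.61). Of 15 DNA replication genes 7 rose (12 adjusted over the list alone, camera adjusted p = 4.44e-07, adjusted p = 0.174 with an estimated correlation), with CDC6 at 1.11. Of 13 NRF2 targets 6 rose (8 adjusted over the list alone, camera adjusted p = 4.38e-05, adjusted p = 0.174 with an estimated correlation), with TXNRD1 at 1.36, and of 11 heat shock genes 6 rose, also adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.0533 with an estimated correlation), with HSPH1 at 1.00. Fatty acid synthesis (4 of 13 fell, also adjusted over the list alone, where 1 rose, FADS2 -1.06, camera adjusted p = 8.38e-06, adjusted p = 0.149 with an estimated correlation) was lower. The ER chaperones SDF2L1 (0.87), HYOU1 (0.78) and HSPA5 (0.58) rose, 3 of the 19 genes of the unfolded protein response (5 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.58 with an estimated correlation). CPLX2 (2.33), HAMP (2.22, in the acute phase and iron lists) and TIMP1 (2.19) were also among the largest rises, and MEP1A (-1.94), SMIM3 (-1.92) and ITIH1 (-1.85, in the secreted protein list) among the largest falls. Junction reads called 11 genes in sgOST4, all also called from RPM in the same direction, among them APOC3 (log2 -1.72, edgeR adjusted p = 0.00907), TF (log2 -1.31, edgeR adjusted p = 7.51e-05) and the chemokine CCL20 (edgeR adjusted p = 0.00926). The extent of the change rested on replicate 2 of sgOST4: without it 25 genes were called, and 9 of the 67 named genes stayed called (PCSK9, S100A11, CPLX2, TIMP1, SMIM3, PFKFB4, NDRG1, ANKRD1 and KRT19) with 18 of 19 lists. Without the serum libraries 18 named genes and 13 lists stayed called, without the starved ones 45 and 16, without sgCTRL replicate 1 43 and 16, without sgCTRL replicate 2 56 and 18, and without replicate 1 66 and 18. Those list counts are at the preset correlation: of the 7 lists called with an estimated one, 1 stayed called without replicate 2, 0 without the serum libraries, 2 without the starved ones, 1 without either sgCTRL replicate and 6 without replicate 1.

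In sgHYOU1, genes of the ATF4 stress response were higher, and genes of hypoxia and of cholesterol synthesis lower. SLC3A2, a subunit of amino acid transporters, stood at 287 ± 117 RPM against 103 ± 32.6 in sgCTRL (SD, n = 4 libraries each, log2 1.42, limma adjusted p = 1.7e-06), WARS1, a tRNA synthetase, at 78.9 ± 23.7 against 24.3 ± 19 (log2 1.88), and HSPA5, the ER chaperone BiP, at 1272 ± 463 against 594 ± 106 (log2 1.04, limma adjusted p = 1.4e-05). PFKFB4, a hypoxia-driven regulator of glycolysis, stood at 16.8 ± 8.87 RPM against 62.3 ± 7.94 (log2 -1.97, limma adjusted p = 1.01e-06). HMGCS1 fell by 0.81 (limma adjusted p = 0.00345) and PCSK9 by 0.64 (limma adjusted p = 0.01). LDLR lay at -0.57 on the log2 scale and was not called (limma adjusted p = 0.161).

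Of 16 ATF4 response genes, 7 rose in sgHYOU1 (10 adjusted over the list alone, camera adjusted p = 8.6e-10), with DDIT3 at 1.40, SESN2 at 1.34 and SLC7A11 at 1.06. Of 18 genes of glycolysis and hypoxia 7 fell (14 adjusted over the list alone, camera adjusted p = 6.58e-21), with CA9 at -1.93, NDRG1 at -1.40 and BNIP3 at -0.78. Of 20 cholesterol synthesis genes 7 fell (14 adjusted over the list alone, camera adjusted p = 1.11e-17), with TM7SF2 at -0.75 and FDFT1 at -0.72, and of 14 genes of LDL uptake and sterol sensing 2 fell (5 adjusted over the list alone, camera adjusted p = 4.77e-05), INSIG2 at -1.004 and PCSK9. These 4 lists were also called with an estimated correlation (camera adjusted p from 0.00294 to 0.0402). Of 19 genes of the unfolded protein response 3 rose, HSPA5, SDF2L1 (0.99) and HERPUD1 (0.65), and 10 adjusted over the list alone (camera adjusted p = 6.72e-08, adjusted p = 0.211 with an estimated correlation). Of 19 secreted proteins 3 fell (7 adjusted over the list alone), TF by 0.91, ITIH1 by 1.38 and TTR by 0.65 (camera adjusted p = 7.17e-09, adjusted p = 0.182 with an estimated correlation), and the junction reads called TF too (edgeR adjusted p = 0.000322). Of 13 fatty acid synthesis genes 3 fell (4 adjusted over the list alone), with ACSS2 at -0.95 (camera adjusted p = 4.77e-07, adjusted p = 0.0817 with an estimated correlation). HAMP (1.74), CPLX2 (1.62), MT1X (1.62) and GPD1 (1.55) rose, and PLA2G2A (-2.18), TINAGL1 (-1.67) and SMIM3 (-1.55) fell. Here too replicate 2 carried much of the change: 19 genes were called without it and 336 without replicate 1. Of 43 named genes and 16 lists, 5 and 8 stayed called without replicate 2, 39 and 15 without replicate 1, 5 and 11 without the serum libraries, 22 and 11 without the starved ones, 27 and 9 without sgCTRL replicate 1, and 21 and 13 without sgCTRL replicate 2. Of the 4 lists called with an estimated correlation, 0 stayed called without replicate 2 or without the serum libraries, 4 without the starved ones, 1 without either sgCTRL replicate and 2 without replicate 1.

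The changes of sgOST4 and sgHYOU1 overlapped, with 60 genes higher in both, 60 lower in both and 0 opposite. Across genes, the deviations of sgHYOU1 replicate 2 correlated with r = 0.52 to 0.60 with those of sgOST4 replicate 2 and with 0.19 to 0.39 with those of sgOST4 replicate 1, and the deviations of sgHYOU1 replicate 1 with -0.04 to 0.13 with those of any sgOST4 library. The comparisons that follow take no account of a shared replicate number. Independent lists of these sizes would share 4.4 and 1.7, and 100 simulated sets of unchanged lines against the same controls shared 0 on average. Genes in those sets were drawn independently, with no structure shared between libraries beyond the controls. Neither their overlap nor their correlation below allows for such structure. Across genes the log2 changes correlated with r = 0.74 where simulated unchanged lines gave 0.5, and their covariance was 0.1443 against 0.0516, a difference of 0.0927. With sgOST4 set against sgCTRL replicate 1 and sgHYOU1 against replicate 2, r was 0.19 with 18 and 30 shared genes, and with the replicates exchanged 0.24 with 14 and 32. Genes are not independent replicates.

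The sgLDLR line had high metallothionein mRNA and lower FOXO-type genes, while the 20 cholesterol synthesis genes were not called as a list (median -0.02, camera adjusted p = 0.468). MT1E stood at 990 ± 229 RPM against 261 ± 142 (SD, n = 4 libraries each, log2 2.16), MT1F at 576 ± 121 against 190 ± 147 (log2 2.12) and MT1G at 1405 ± 333 against 660 ± 732 (log2 2.504, limma adjusted p = 1.35e-06). MT1G stood at 1147 RPM against 57.57 in serum and at 1663 against 1262 after starvation. IGFBP1, a secreted insulin-repressed protein, fell to 826 ± 145 RPM against 2006 ± 251 (log2 -1.29, limma adjusted p = 6.3e-06). LDLR itself stood at 54 ± 14.1 RPM against 94.4 ± 47.5 and was not called (log2 -0.68, limma adjusted p = 0.124). PCSK9 (0.10), HMGCR (0.12) and HMGCS1 (-0.03) were not called.

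Of 11 metallothionein and zinc genes, 5 rose in sgLDLR (6 adjusted over the list alone, camera adjusted p = 1.54e-08, and adjusted p = 0.0168 with an estimated correlation). In the starved libraries alone the list was not called (camera adjusted p = 0.233). Of 8 FOXO and insulin-repressed genes, IGFBP1 and G6PC1 (-2.12) fell (4 adjusted over the list alone, camera adjusted p = 1.58e-06, and adjusted p = 0.0168 with an estimated correlation). Of 15 DNA replication genes 2 rose, PCNA by 0.89 and MCM3 by 0.68 (10 adjusted over the list alone, camera adjusted p = 1.88e-08, adjusted p = 0.124 with an estimated correlation). TAGLN (2.18) rose, and the mitochondrial transcript MT-TL1 (-1.34), MEP1A (-1.34) and the kinase PIM1 (-1.24) fell. None of the 18 named genes stayed called in the starved libraries alone, 10 did in serum alone, 11 without either sgCTRL replicate, 5 without replicate 1 (9 genes called in all) and 7 without replicate 2 (13 genes). MT1E, MT1F, MT1G, MT1X (2.26) and IGFBP1 stayed called without either replicate of sgLDLR. With an estimated correlation, neither of the 2 lists stayed called without the serum libraries, sgCTRL replicate 1 or replicate 2, 1 did without sgCTRL replicate 2, and both did without the starved libraries or replicate 1.

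**Figure D4:**
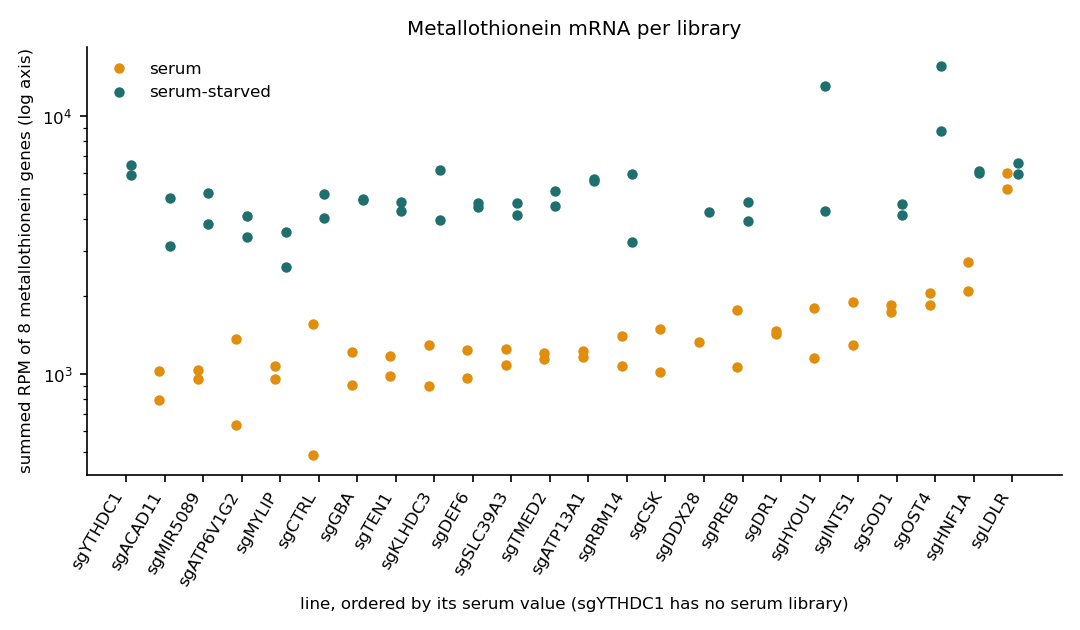
Summed RPM of 8 metallothionein genes in each library (y axis, log scale; orange serum, teal serum-starved), with lines on the x axis in the order of their serum value. Both serum libraries of sgLDLR lie among the starved libraries of other lines, at a mean of 5637 RPM against 911.6 to 2410 RPM in the serum samples of other lines.

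Progenitor and biliary markers were higher as a list in the lines targeting HNF1A, SOD1, CSK and DR1 at the preset correlation, and in sgSOD1 alone of these with an estimated one. In sgHNF1A the largest rises were PLA2G2A, a secreted phospholipase (213 ± 116 RPM against 13.5 ± 7.14, SD, n = 4 libraries each, log2 3.87, limma adjusted p = 4.19e-06), MAP3K12 (log2 2.13) and MATN3, a matrix protein (229 ± 38.7 against 55.3 ± 14.6, log2 2.06). Of 14 HNF1A-dependent genes none was called in sgHNF1A over all genes and 2 fell adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.000224, adjusted p = 0.0817 with an estimated correlation). AFP, the fetal albumin-like protein, fell to 7185 RPM against 12480 (log2 -0.75, limma adjusted p = 0.00706, junction reads edgeR adjusted p = 0.00338). AK4 (-1.25), DDC (-1.21), CX3CL1 (-1.02), LSS (-0.93) and PCSK9 (-0.63) fell. Of 11 progenitor and biliary markers 3 rose, S100A6 (1.41), LGALS1 (1.23) and KRT19 (1.14), and 5 rose with 1 falling adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.174 with an estimated correlation).

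In sgSOD1, 5 of these 11 markers rose (6 adjusted over the list alone, camera adjusted p = 4.51e-09, and adjusted p = 0.021 with an estimated correlation), with LGALS1 at 602 ± 200 RPM against 254 ± 129 (SD, n = 4 libraries each, log2 1.34, limma adjusted p = 2.82e-06), S100A6 at 1.14, SPP1 at 1.09 and KRT19 at 1.006. Of 12 immediate early genes, IER3 (0.88) rose and 4 rose adjusted over the list alone (camera adjusted p = 2.37e-05, adjusted p = 0.0817 with an estimated correlation). CPLX2 (1.95), IGFBP2 (1.65) and AKAP12 (1.58) rose, and HPX (-1.90), RHBG (-1.31), SARDH (-1.18), SERPINC1 (-1.11) and IREB2 (-1.08) fell. In sgCSK, measured in serum only, MAP3K12 (3.07), AKAP12 (38.4 against 4.5 RPM, log2 2.84, limma adjusted p = 5.9e-07), CPLX2 (2.77), DMAC2L (2.07) and IGFBP2 (2.06) rose, and KNG1 (-2.97), DOLPP1 (-2.85), ATP2B1 (-2.13) and SARDH (-1.77) fell. The sgCTRL value of AKAP12 is low beside the serum mean over lines of 21.3 ± 11.3 RPM (SD, n = 20 lines). Of the 119 genes called in sgCSK 46 were also called against all other lines, and of the 62 in sgDR1 11. Against that reference AKAP12 was called in sgCSK (log2 1.02, limma adjusted p = 0.0233), and CPLX2 was called in sgOST4 but not in sgHYOU1, sgSOD1, sgCSK or sgDR1. Of 12 immediate early genes, EGR1 and IER3 rose (3 adjusted over the list alone), the second at 854 ± 113 RPM against 411 ± 27.9 (SD, n = 2 libraries each, log2 1.05, camera adjusted p for the list = 0.00218, adjusted p = 0.215 with an estimated correlation). EGR1 was listed at 0 in both sgCTRL serum libraries. LGALS1 (1.263) was the 1 called member of the progenitor list in sgCSK, where 2 rose adjusted over the list alone (camera adjusted p = 0.00751, adjusted p = 0.35 with an estimated correlation). In sgDR1, also serum only, LGALS1 stood at 513 ± 62.3 RPM against 145 ± 44.6 (SD, n = 2 libraries each, log2 1.85, limma adjusted p = 6.72e-06), the 1 called progenitor marker, also adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.273 with an estimated correlation). LAIR2 (2.74), TAGLN (2.73), CPLX2 (2.61), MELK (2.07) and the acute phase gene FGL1 (1.28) rose, and RHOBTB3 (-2.22), GOLGA2 (-1.58) and AKR1C2 (-1.21, whose tags can be shared with AKR1C1) fell.

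None of these lines was stable to every left-out replicate. In sgHNF1A, of 22 named genes 0 stayed called in the starved libraries alone, 20 in serum alone, 17 and 8 without sgCTRL replicates 1 and 2, and 13 and 4 without its own replicates 1 and 2 (30 and 17 genes called in all). In sgSOD1 the numbers were 0, 13, 14, 7, 4 and 13 of 19, in sgCSK 11, 7, 9 and 10 of 17 without the sgCTRL and own replicates, and in sgDR1 11, 1, 7 and 2 of 12. The edgeR test on recovered reads called 9 genes in sgCSK, 14 in sgDR1, 22 in sgSOD1 and 42 in sgHNF1A. The progenitor list kept its call in sgSOD1 and sgHNF1A under each left-out replicate or condition at the preset correlation (with an estimated one sgSOD1 lost it under each), and in sgCSK and sgDR1 it was lost without sgCTRL replicate 1 (camera adjusted p = 0.195 in sgCSK, 0.132 in sgDR1) and without replicate 1 of the line (0.111 and 0.075).

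In sgPREB, whose target starts the COPII coat, genes of LDL uptake and of cholesterol synthesis were lower. LDLR fell to 42.5 ± 7.61 RPM against 94.4 ± 47.5 (SD, n = 4 libraries each, log2 -0.99, limma adjusted p = 0.0178), SREBF2, the regulator of sterol genes, by 0.82 and SCARB1, an HDL receptor, by 0.78. The sgCTRL level of LDLR was high after starvation (132.64 RPM against a median of 92.83 over lines) and near the median in serum (56.08 against 56.58). LDLR, SREBF2 and SCARB1 were the 3 called of 14 genes of LDL uptake and sterol sensing (7 fell adjusted over the list alone, camera adjusted p = 1.29e-06, and adjusted p = 0.0172 with an estimated correlation). Of 20 cholesterol synthesis genes DHCR7 (-0.75), FDFT1 (-0.71) and TM7SF2 (-0.70) fell (14 adjusted over the list alone, camera adjusted p = 6.25e-16, and adjusted p = 0.0168 with an estimated correlation). Of 18 genes of glycolysis and hypoxia PFKFB4 (-1.02), NDRG1 (-0.81) and GAPDH (-0.54) fell (9 adjusted over the list alone, camera adjusted p = 6.4e-11, and adjusted p = 0.0259 with an estimated correlation). ACSS2 (-0.71), FASN (-0.67) and SCD (-0.61) fell among 13 fatty acid synthesis genes (6 adjusted over the list alone, where 1 rose, camera adjusted p = 2.15e-06, adjusted p = 0.113 with an estimated correlation). The ER stress gene HERPUD1 rose by 0.72. The list calls for uptake, cholesterol synthesis and hypoxia remained under every left-out replicate at the preset correlation. With an estimated correlation 0 of the 3 remained without the serum libraries or either sgCTRL replicate, 1 without the starved libraries or replicate 1, and 2 without replicate 2. The calls of single genes did not all remain. Of 13 named genes 10 stayed called without sgCTRL replicate 1, 1 without the serum libraries and 0 without the starved libraries, sgCTRL replicate 2 or either replicate of sgPREB.

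In sgMYLIP, whose target marks LDLR for degradation, 10 genes were lower and none higher in limma, with 1108 at an unadjusted p under 0.05, and recovered reads gave 0 in edgeR. Against all other lines 87 genes were called (3 higher and 84 lower), 8 of which were also called against sgCTRL. With median-of-ratios scaling 1 gene was lower than sgCTRL and with quantile scaling 0. The largest falls were CUL5 (-1.41), CX3CL1 (-1.19), BORCS7 (-0.93) and YIF1A (-0.81), against a median gene at -0.12. LDLR lay at -0.30 (limma adjusted p = 0.568). These 4 genes stayed called in serum alone and without replicate 2, 3 of them without sgCTRL replicate 1, and none in the starved libraries alone, without sgCTRL replicate 2 or without replicate 1.

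Against sgCTRL the 20 cholesterol synthesis genes were lower as a list in 20 of the 23 lines, all but sgACAD11 (camera adjusted p = 0.131), sgYTHDC1 (0.149) and sgLDLR. With an estimated correlation 4 lines were called (sgOST4, sgHYOU1, sgHNF1A and sgPREB). The same 4 lines and sgSOD1 were lower when set against the mean of all other lines, where 6 lines were higher, sgLDLR among them. Libraries of sgHNF1A and sgSOD1 lay below the median library in serum and near or above it after starvation. In serum alone 20 lines were lower than sgCTRL and in the starved libraries alone 6. Without sgCTRL replicate 1 the number was 18, and without replicate 2 it was 15. In sgMYLIP, for example, 6 members fell adjusted over the list alone and none over all genes (camera adjusted p = 1.45e-05, adjusted p = 0.222 with an estimated correlation), and in the starved libraries alone the list was not called (camera adjusted p = 0.957).

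**Figure D5:**
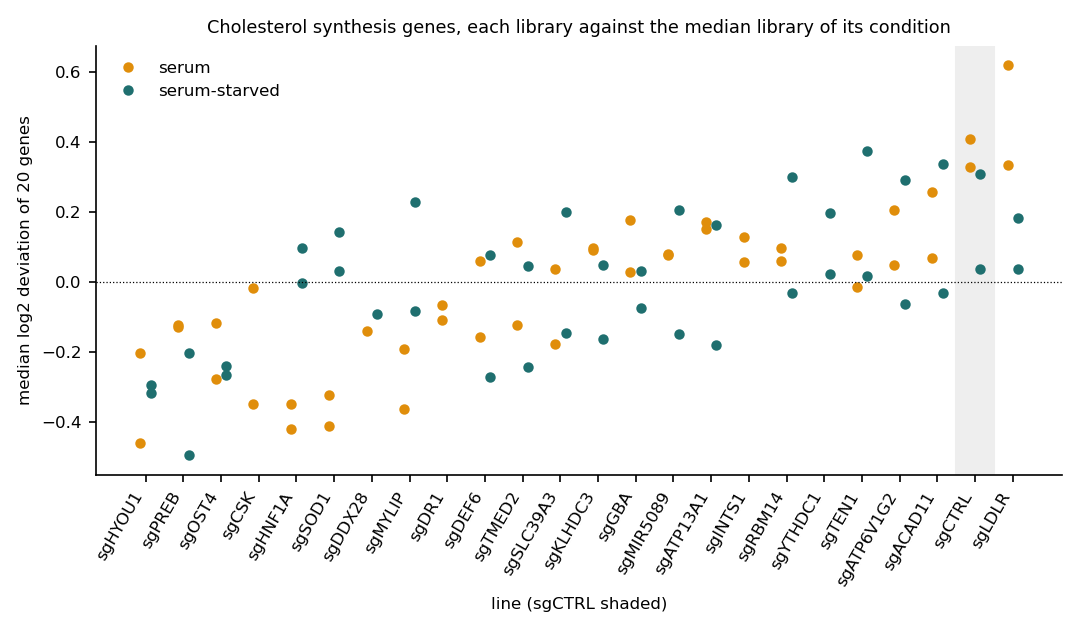
Median log2 deviation of 20 cholesterol synthesis genes from the median library of the same condition (y axis) for each library (points; orange serum, teal serum-starved), with lines on the x axis and sgCTRL shaded. The sgCTRL libraries lie above 0, second only to sgLDLR in the order of lines.

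Summed over lines, camera called 160 of 759 pairs of list and line (53 higher and 107 lower), and 19 (5 and 14) with an estimated correlation. The total ranged from 81 without sgCTRL replicate 1 to 169 without sgCTRL replicate 2. Among lines with few called genes, sgYTHDC1 had higher progenitor and biliary markers (0 called over all genes, 6 higher adjusted over the list alone, median 0.86, camera adjusted p = 5.18e-08, and adjusted p = 0.03 with an estimated correlation), measured in starved cells only. In sgINTS1, 2 of 11 metallothionein and zinc genes rose (5 adjusted over the list alone, camera adjusted p = 0.000701, adjusted p = 0.174 with an estimated correlation).

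The called genes of the lines with 5 or fewer are named here, chosen after their values were seen. A2M, a secreted protease inhibitor, fell in sgSLC39A3 (621 against 1355 RPM) and in sgDEF6 (657 against 1355). ADH4, AGR2, MMACHC and NDUFS5 rose in sgSLC39A3. PGC and SERPINA5 fell and LCN15 rose in sgDEF6. NABP2, TCF7, DEGS1 and SPPL3 fell in sgACAD11, GSTA1 and NPIPA1 (listed at 0) in sgYTHDC1, and RALB, a small GTPase, in sgGBA (12.8 ± 3.02 RPM against 34.1 ± 4.83, SD, n = 4 libraries each). UGGT2, a sensor of glycoprotein folding in the ER, rose in sgTMED2 (15.2 ± 6.95 RPM against 3.44 ± 3.22, SD, n = 4 libraries each). The calls of sgACAD11, sgGBA and sgTMED2 were absent with quantile scaling (0 genes in limma) and from edgeR on recovered reads, and that of sgGBA also with median-of-ratios scaling. Junction reads called CHCHD10 (log2 3.12), ZFAS1 (log2 0.96) and TF in sgHYOU1, each also called from RPM in the same direction.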

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

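The pseudocounts for differences between conditions, the tests of the ATF4 list, of mixed RNA and of the metallothionein sums, and the fits of the cholesterol list without single replicates, against all other lines, with a length correction or without shallow libraries, were chosen after the result was seen.

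The difference of a line from sgCTRL was not the same in the 2 culture conditions in 35 pairs of gene and line by limma (23 genes), all with a lower value in starved cells than in serum. With a pseudocount of 5 RPM 12 pairs were called, and with 0.25 RPM 129. On simulated data this test also called 7 unchanged genes, more than 5% of its calls. The log2 values below are the starved difference minus the serum difference. AKAP12 was called in sgATP13A1 (-2.512), sgDEF6 (-2.496), sgKLHDC3 (-2.55), sgMIR5089 (-2.675), sgMYLIP (-2.819), sgOST4 (-3.385), sgPREB (-2.552) and sgRBM14 (-2.655), and in sgCTRL itself AKAP12 stood at 4.5 RPM in serum and 95.4 RPM in starved cells. TNNC1 was called in sgATP13A1 (-3.544), sgMYLIP (-3.213) and sgSOD1 (-3.533), VPS53 in sgATP13A1 (-3.345) and sgGBA (-3.801), and MOSMO in sgDEF6 (-3.135), sgRBM14 (-3.797) and sgSLC39A3 (-3.235). In sgCTRL these genes too were low in serum, with 1.145 against 29.1 RPM starved for TNNC1, 1.88 against 15.4 for VPS53 and 4.82 against 26.81 for MOSMO, so each repeated call shares a low control value. In sgDDX28 each condition has 1 library, so the spread behind the test comes from other lines alone and each library is assumed to vary like theirs. ZNF142, DLEU2 and NEK2 were listed at 0 there after starvation, and their values depend on the pseudocount. The called genes there were ZNF142 (-5.263), SPOP (-3.525), RTF1 (-3.03), RNPEPL1 (-3.245), ZNF267 (-4.267), DLEU2 (-6.883) and NEK2 (-5.431). In sgMYLIP they were also MAP3K20 (-3.745), GBF1 (-2.895), PRMT7 (-4.244), MAP3K12 (-4.155) and REEP4 (-2.643). The others were INTS13 in sgKLHDC3 (-3.286), LGALS3 in sgOST4 (-2.129), ATP1A1-AS1 in sgSOD1 (-3.748), and MT1G (-4.141), MT1B (-4.463), MT1F (-3.025) and MT1M (-5.486) in sgLDLR. There MT1G and MT1F were above sgCTRL in serum (1147 against 57.57 and 669.7 against 65.91 RPM), while MT1B and MT1M were below it after starvation (12.98 against 114.7 and 7.175 against 35.42 RPM), and both were listed at 0 in serum in sgCTRL, so that their values depend on the pseudocount too. Several genes called in 1 line were low in serum in sgCTRL too. Among them were PRMT7 (1.88 RPM against 15.56 starved), MAP3K20 (3.675 against 19.06), INTS13 (6.7 against 34.22) and ATP1A1-AS1 (3.35 against 16.12). In sgCTRL GBF1 (22.88 against 29.98), RTF1 (26.56 against 35.2) and SPOP (30.56 against 24.8) differed less. In the serum sgCTRL libraries 1 read was worth 1.4703 and 2.2904 RPM. Every gene tested here shares the same 4 sgCTRL libraries, and 316 differences (309 lower, 7 higher) were called without the libraries under 500000 reads, among them serum sgCTRL replicate 2. In 6 lines limma called 0 genes, with 558 (sgACAD11), 445 (sgATP6V1G2), 421 (sgHNF1A), 442 (sgHYOU1), 390 (sgTEN1) and 425 (sgTMED2) at an unadjusted p under 0.05, and no other tool was run for this contrast.

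A splice junction that the annotation does not hold appeared in the targeted gene of sgOST4. It spans chromosome 2 from 27071445 to 27071600, inside OST4, and was crossed by 4 of 226 junction reads of the gene in the 4 sgOST4 libraries (both starved ones), by 1 of 6108 in all other libraries and by 0 of 163 in sgCTRL. Fisher's exact test gave a one-sided p of 7.68e-06, adjusted p = 0.000261 over 34 junctions in targeted genes. That test pools 4 reads from 2 libraries as independent and covers counting error, not the spread between libraries. Where the guide lies is not given in the sources used here, so whether the junction lies at the edit was not tested.

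The cholesterol synthesis list was lower than in sgCTRL in 20 of 23 lines. A single deviating sgCTRL replicate would leave fewer than 5 lines without it, and 18 and 15 lines were called without replicates 1 and 2. A trend with transcript length was argued against by the 19 lines called after its removal (lengths known for 8381 of the genes, 99.9%), and shallow libraries by the 18 called without those under 500000 reads. Against the mean of all other lines 11 lines were called, 6 of them higher, so a high level in 3 of the 4 sgCTRL libraries (0.329 and 0.409 above the median library in serum, 0.308 and 0.036 after starvation) is a candidate explanation for most of the 20 lines, while sgHYOU1, sgOST4, sgPREB, sgHNF1A and sgSOD1 were lower against either reference. In sgHNF1A and sgSOD1 this held for the serum libraries (-0.348 and -0.421, -0.41 and -0.322 from the median library). Their starved libraries lay near or above it (0.097 and -0.002, 0.031 and 0.143). Among starved libraries replicate 2 lay above replicate 1 in most lines, so the 0.308 and 0.036 of sgCTRL also follow replicate number. Whether a property of the sgCTRL line or wells set the high sgCTRL level stays open, since there is 1 control line.

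Replicate 2 of sgHYOU1 resembled sgOST4: its libraries differed from sgOST4 in 4 genes by limma, where the replicates of sgOST4 differed from each other in 6 and sgHYOU1 replicate 1 differed from sgOST4 in 122. The test of a wrong label written beforehand was met by that 4, as a wrong label needs no more than 6. Against it stands only the ATF4 response list, tested afterwards, which lay 0.745 above the sgOST4 libraries (log2, camera adjusted p = 1.65e-06 with an estimated correlation) as in replicate 1 (0.467, camera adjusted p = 0.00602 with an estimated correlation), although the sgOST4 replicates themselves lay 0.423 apart (camera adjusted p = 0.321 with an estimated correlation, 0.0117 at the preset one). TRIB3 and SLC3A2, members of that list, were among the 4 genes called in the same comparison, so the list is not separate evidence. Whether the label is wrong therefore stays open. A mixture with sgOST4 RNA would move higher and lower genes by the same share of the way to the RNA mixed in. Toward the mean of both sgOST4 replicates the median shares were 0.618 (42 genes) and 1.078 (13 genes), a difference of 0.46 (95% bootstrap interval over genes 0.231 to 0.68, 10000 draws). But sgHYOU1 replicate 2 correlated more with sgOST4 replicate 2 (r = 0.52 to 0.6) than with replicate 1 (0.19 to 0.39). Unequal shares toward the mean of both therefore do not decide whether RNA was mixed. A difference between the cultures that gave replicates 1 and 2 may account for part of the effect and was not tested.

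Metallothionein mRNA was high in serum in sgLDLR, with a sum over 8 genes of 5637 RPM against 911.6 to 2410 RPM in the other lines (sgCTRL 1024). Starved cells or RNA in that sample were argued against by 13 other genes of the serum response, whose median share of the way from serum to starved was -0.029 and -0.119 in its 2 libraries. Reads moved between copies were argued against by the sum itself, which was 2.34 times that of the highest other line. After starvation the sum was 6296 RPM against a median of 4517 in other lines, a ratio to serum of 1.12 where other lines had at least 2.41 (median 4.11). The sgLDLR genotype may raise metallothionein mRNA in serum, a hypothesis found and tested on the same 4 libraries of 1 line, and the zinc content of its cultures was not measured.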

How the results depend on the processing

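The fits of the sgRNA lines with recovered reads, those without shallow libraries or with a length correction, the pseudocounts for differences between conditions, and the lists under left-out replicates or against all other lines were chosen after the result was seen. The serum comparison kept its side of the threshold for most named genes: of 139 genes followed, 1262 gene and setting pairs were the same, 11 lost the call and 4 changed sign, all with junction reads (DAD1 0.08132, OSTC 0.02464, RPS2 -0.001252 and RPL8 -0.06219). Junction reads called 519 genes where RPM called 4224, over 1339 genes against 8388. In the sgRNA lines 264 genes were followed, 3102 pairs were the same, 1000 lost the call, 33 gained it, 120 not called moved by more than their standard error and 5 changed sign: MAP3K12 in sgDR1 (-0.3426 against all other lines), RRM2 in sgOST4 (-0.05548 in starved libraries alone, up to 1.803 in serum alone), and on junction reads AC092069.1 in sgHNF1A (-0.4187), INSIG2 in sgOST4 (0.3793) and MANF in sgSOD1 (0.1244). The cause was not tested.

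Against all other lines 2655 differences were called in place of 1193, with 1288 in sgOST4, 449 in sgHYOU1, 220 in sgLDLR and 32 in sgDR1. With the replicate number as a block the total was 1903 (sgHYOU1 327, sgCSK 209, sgSOD1 116, sgHNF1A 113, sgLDLR 111, sgDR1 96). Over serum and starved samples together, same-numbered libraries did not in general deviate together (correlations of -0.17 to 0.39 over 861 pairs, median 0.06, 34% above 0.1). They were not taken as pairs. On the cholesterol synthesis list, however, starved replicate 2 lay above replicate 1 in every line with both, except sgHNF1A and sgOST4. In sgTEN1 the values were 0.373 and 0.016. Within a line, the difference between replicates correlated between serum and starved libraries with r = 0.31 in sgOST4 and in sgHYOU1, and with -0.11 to 0.14 in the other lines. Junction reads gave 19 in all (sgOST4 11, sgHYOU1 3, sgHNF1A 2, sgLDLR 2, and 0 in sgCSK, sgDR1 and sgSOD1), and 34 with no filter. Recovered reads gave 9 in sgCSK, 14 in sgDR1 and 22 in sgSOD1. Without the libraries under 500000 reads sgHYOU1 had 304, sgLDLR 124 and sgSOD1 33. A pseudocount of 0.25 gave 82 in sgLDLR, one of 5 gave 76 in sgCSK and 27 in sgDR1. A mean of 20 RPM gave 55 in sgCSK and 37 in sgDR1, quantile scaling 61 and 39. The cause was not tested.

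For differences between the conditions, 129 pairs of gene and line were called with a pseudocount of 0.25, 12 with 5, and 316 without the libraries under 500000 reads, against 35. Lists called with an estimated correlation were 3 of 17 in the serum comparison and 19 of 160 in the lines. The cholesterol list was called in 4 lines with an estimated correlation, 11 against all other lines and 10 with the length trend also removed, against 20.

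Leaving out each line, condition or replicate gave ranges of 4090 to 4275 genes and 17 to 17 lists for serum, 12 to 12 junction calls, and 100 to 2315 calls over the lines. Per line they were 25 to 569 in sgOST4, 8 to 336 in sgHYOU1, 78 to 259 in sgCSK, 15 to 159 in sgDR1, 0 to 131 in sgSOD1, 1 to 168 in sgHNF1A and 2 to 119 in sgLDLR. List calls ranged from 81 to 169 and the lines with the cholesterol list from 6 to 21. A group left with 1 library is assumed to vary like the others. At this depth a line against 4 sgCTRL libraries misses many changes of 2-fold: 52% to 56% of simulated ones were called.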

Other observations

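The fits of the lists in single lines against all other lines, without shallow libraries and with a length correction, and the choice of sgDDX28, were made after the result was seen. In sgDDX28, whose target is a mitochondrial RNA helicase, the 13 mitochondrially encoded mRNAs were higher as a list, in 2 libraries (1 per condition) with no replicate, so each test below rests on the spread of other lines. None was called over all genes and 3 rose adjusted over the list alone, with a median of 0.36 on the log2 scale (camera adjusted p = 5.81e-08, adjusted p = 0.0817 with an estimated correlation). Against all other lines the list was called too (camera adjusted p = 1.68e-06), as it was after removal of the length trend (camera adjusted p = 0.000541) and without the libraries under 500000 reads (camera adjusted p = 1.19e-07). The list is not particular to this line: against sgCTRL it was called higher in 8 other lines at the preset correlation, with a median of 0.415 in sgOST4 (camera adjusted p = 0.000417, adjusted p = 0.273 with an estimated correlation), and sgOST4 was also higher against all other lines (camera adjusted p = 0.0435). In sgLDLR the cholesterol synthesis list, near sgCTRL, was higher than the mean of all other lines (4 of 20 genes rose, median 0.345, camera adjusted p = 3.54e-05). Its libraries lay 0.334 and 0.619 above the median library in serum (ranks 3 and 1) and 0.037 and 0.181 after starvation (ranks 17 and 10).

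Several lists were not called between serum and starved cells although members moved both ways. FTL, the light chain of ferritin, rose from 5451 to 11110 RPM (log2 1.04) and FTH1 by 0.70, while the iron exporter SLC40A1 fell by 0.96, among 9 iron genes of which 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.117). FABP1, a fatty acid carrier, rose from 1811 to 3754 RPM (log2 1.06), the lipid droplet gene CIDEC by 1.75, and ACOX1, which starts peroxisomal oxidation, fell by 0.60, among 12 PPARA targets of which 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.388). Of 14 p53 targets 3 rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.15), TP53INP1 by 1.42 and MDM2 by 0.46, while CDKN1A rose by 0.31. In the bile acid list NR0B2 (-0.78) and NR1H4 (-0.64) fell and the exporter SLC51A (0.97) rose, as 1 of 6 genes against 4 falling, also adjusted over the list alone (camera adjusted p = 0.117). NFKBIA fell by 1.10 in a NF-kB list of 6 where 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.81).

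Other splits of the libraries were fitted for the serum comparison and for the lines with 4 libraries, where genes or lists were called. Chance can be excluded for the genes of the serum comparison: of 100 splits, 1 gave as many genes (4224, highest other 1354) and 1 as many junction genes (519, highest other 155). For its lists 2 of the 100 splits gave as many (17, highest other 17), so that another split reached the real number. In fits of 4 libraries of a line and 4 of sgCTRL, 34 splits were counted. Only the real split gave as many genes in sgOST4 (461, highest other 351), sgHNF1A (59 and 51), sgLDLR (55 and 46) and sgPREB (46 and 30), and as many lists in sgSOD1 (9 and 7) and sgLDLR (15 and 12). That is 1 of 34 splits in each, the smallest share these splits can give. The lines were read 1 by 1 with no adjustment over them, so chance is not excluded for any single line. Chance cannot be excluded, since more than 1 split gave as many, for the genes of sgHYOU1 (192 and 199, 2 splits), sgSOD1 (57 and 106, 3 splits), sgRBM14 (30 and 127, 3 splits), sgMYLIP (9 and 507, 10 splits), sgSLC39A3 (2 and 34, 7 splits), sgDEF6 (4 and 32, 7 splits) and sgGBA (1 and 35, 15 splits). Nor can it for the lists of sgOST4 (20 and 21, 3 splits), sgHYOU1 (18 and 19, 3), sgHNF1A (11 and 11, 2), sgPREB (10 and 13, 5), sgRBM14 (3 and 3, 3), sgMYLIP (4 and 5, 4), sgSLC39A3 (6 and 8, 2), sgDEF6 (5 and 6, 4), sgGBA (2 and 5, 6), sgTMED2 (4 and 7, 6), sgATP13A1 (10 and 10, 2), sgKLHDC3 (9 and 12, 2) and sgMIR5089 (5 and 5, 4). These fits take serum as an additive term and called 0 genes in limma in the real grouping of sgACAD11 and sgTMED2 and 0 lists in that of sgATP6V1G2 and sgTEN1, so that all 34 splits gave as many and say nothing about those calls (highest other 190, 25, 6 and 5). Chance cannot be excluded either for junction genes in sgOST4 (11 and 13, 2 splits), sgHYOU1 (3 and 3, 2) and sgHNF1A (1 and 2, 9). For sgLDLR and sgPREB edgeR called 0 junction genes in these fits, in the real grouping and in all 34 splits (2 and 1 in the fit over all libraries), so the splits say nothing about chance there. The split with 507 genes for sgMYLIP set serum sgCTRL replicate 1 with 3 libraries of the line. Serum sgCTRL replicate 2 (436603 reads) was thus apart from the other serum libraries, and starved sgMYLIP replicate 1 (468501 reads) from the other starved ones. The split with 190 genes for sgACAD11 set apart its serum replicate 2 (344431 reads), the shallowest library. Those with 127, 35, 34 and 32 genes also set serum sgCTRL replicate 2 apart. These splits point to a structure among the libraries, for which depth is a candidate that was not tested.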
